A study of Mus musculus with 12 samples.

How the data were processed

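The deposited table held 23077 mouse genes, identified by Ensembl gene and symbol, in 12 columns. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.10 and quantified with Salmon 1.10.3 against GRCm39. The tool that summed transcripts to genes and scaled the libraries is not given in the sources used here. The values deposited by the authors are signal: gene counts already divided by a constant per library. Every value of all 11 libraries used was a whole multiple of the smallest nonzero value in its library (100% at a tolerance of 0.001). The reads per library could therefore be recovered (14872639 in the smallest library). The heading of SDDIR B appeared on 2 columns with identical values in all 23077 rows, so it was counted once and SDDIR had 2 libraries. Whether these values are of replicate B or replicate C cannot be settled from the table, and the library is called SDDIR B throughout, after its heading. The remaining SDDIR sample was not analysed here. The plan had counted 12 libraries. NIL, SDD and RISDD had 3 each. Rows for the ERCC spike-ins, the SNAP tag, GFP and the viral cassettes were not used here.

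Per the labels' protocols, cells were infected with retroviruses, moved to N3 medium on day 3 and collected on day 4. RepSox was added in every group except NIL. NIL cells were sorted as live single cells and the others as SNAP-stained, SNAP-positive cells. RNA of sorted cells was selected by polyA and made into NEBNext Ultra II Directional libraries.

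Genes with a value of at least 10 in at least 3 libraries were tested (14207 genes). All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend and robust variance moderation. A gene changed when its Benjamini-Hochberg adjusted p was under 0.05, and a 2-fold change also needed an absolute log2 change of at least 1. A total of 34 gene lists were fixed before the data were examined, together with the groups, the comparisons, the tests, the alternatives listed first below and the rule for naming genes. Lists with at least 5 tested genes (31) were tested with camera at a preset correlation of 0.01, and again with the correlation estimated for each list. List p-values were adjusted over the 31 lists of a comparison. Counts of list members use the adjustment over all tested genes, and counts adjusted over the list alone are given beside them in the report and for the comparisons with NIL.

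The text names the 5 delivered factors, and in each comparison the 5 largest rises and 5 largest falls that passed, had a mean of at least 100 in either group and did not overlap between groups. From each called list, and from 7 lists chosen in advance, it names up to 3 members that passed with the largest absolute log2 change at that mean, and from other lists at most 1. Genes printed from a list follow that order. Results of some genes that the rule allows are not reported here. Mnx1 was added after its values were seen. The comparisons of SDDIR and RISDD with NIL were also added after the planned results were seen.

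The alternatives were upper-quartile and quantile scaling, pseudocounts of 0.5 and 10, no filter and a minimum value of 50, a fit with neither trend nor robust moderation, array weights, a fit of only the 2 groups compared, a replicate block, DESeq2 1.42.0 on the recovered reads for counts of changed genes, and each library left out in turn. Added after the data were seen were edgeR 4.0.16 on the recovered reads, DESeq2 for fold changes of named genes, a correction of each library for its trend with GC content, and the repeated column counted as a library. GC content came from reference transcripts of another build, matched for 14177 of the 14207 genes. Left-out libraries and regrouped samples were refitted with the same settings.

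The code was tested on simulated data. Each gene's spread was taken from these libraries within groups, capped, and set equal in all groups. A single library that stands apart, as NIL C does below, was not simulated. Of 100 genes changed 2-fold it recovered 62, 47, 62 and 55 in the 4 comparisons (SDD against NIL, SDDIR against SDD, RISDD against SDD, RISDD against SDDIR), and of 100 changed 4-fold 93, 86, 88 and 89. The changed genes all had a mean value of at least 100, so recovery of genes with lower values was not measured. False calls were 1.90%, 5.67%, 4.46% and 3.36% of all calls. A shifted gene list was called in all 4 comparisons, and 0 of 30 other lists. Genes were drawn independently and the lists were random, so this does not measure false calls for lists of correlated genes.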

Results

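Mouse embryonic fibroblasts with the Hb9::GFP reporter, which reports Mnx1 (Hb9), a transcription factor of motor neurons, were sampled while being converted to induced motor neurons. All 4 groups received a retrovirus with the conversion factors Ngn2 (gene symbol Neurog2), Isl1 and Lhx3, called NIL. The group named NIL received nothing else. The SDD group also received p53DD, a dominant-negative fragment of p53, fused to a SNAP tag. The SDDIR and RISDD groups received constitutively active HRAS on the same transcript as that fusion, joined by an internal ribosome entry site (IRES). HRAS followed the IRES in SDDIR and preceded it in RISDD. The p53DD fusion therefore preceded the IRES in SDDIR and followed it in RISDD. A protein encoded after an IRES is usually made at a lower level. Per the labels, all cells were collected 4 days after infection. Every group except NIL was also given RepSox, an inhibitor of the TGF-beta receptor, on day 3, and was sorted for the SNAP tag. The deposited values were gene counts already scaled to each library, called signal here. Changes are limma tests on log2(value + 1), and all folds are on that scale. Samples are labelled as biological replicates A to C with no further statement of separate cultures, so the p-values measure only the spread between these samples.

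The libraries separated first by HRAS group. The first principal component held 54.3% of the variance and placed NIL and SDD libraries at -83.0 to -52.3, the 2 SDDIR libraries at 43.3 and 45.2, and RISDD at 97.7 to 103. NIL C stood apart on the second component (19.1% of the variance), at -114 against -17.1 to 53.5 for all others. Its mitochondrially encoded genes held 0.537% of the signal, against 3.62% in NIL A and 4.00% in NIL B. Its spread from NIL A and NIL B was 204 and 209 times that of read sampling (chi-square per degree of freedom), against 8.46 to 28.7 for every other pair within a group. NIL C was kept, and what leaving it out did is given with each comparison.

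**Figure D1:**
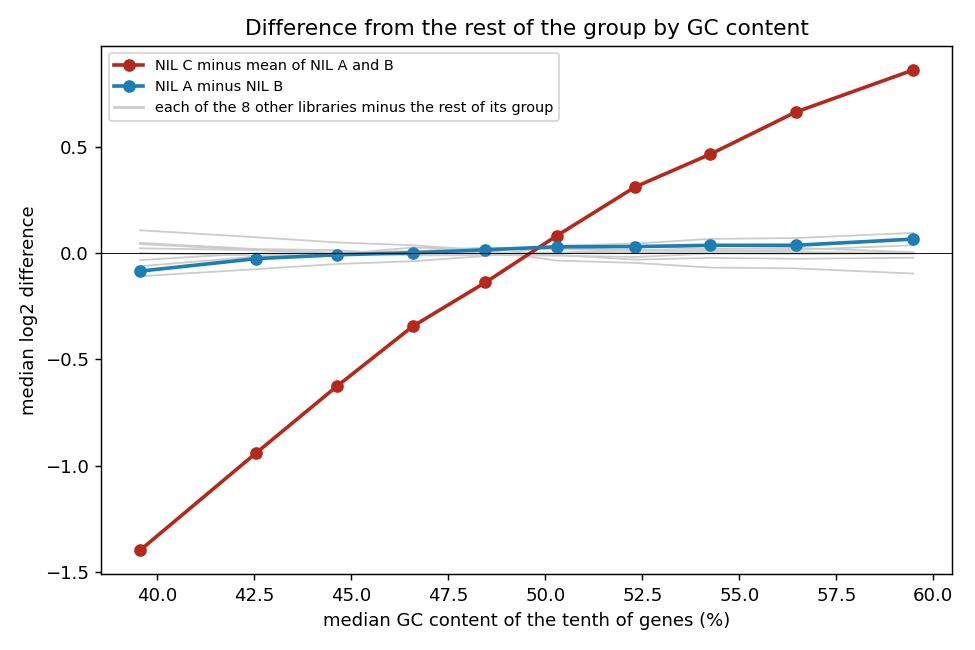
Median log2 difference by GC content (%) in 10 equal bins of the 10642 tested genes with a GC value and a mean of at least 100. Lines show NIL C against NIL A and NIL B (red), NIL A against NIL B (blue) and each other library against the rest of its group (grey). NIL C ran from -1.40 in the lowest bin to 0.86 in the highest.

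The delivered factors were read from the mouse gene rows. Trp53, whose row also counts the p53DD fragment, was 37612 ± 4562 in SDD and 3201 ± 419 in NIL (SD, n = 3 each), 11.7-fold higher (adjusted p = 9.66e-07). It was at 33173 in SDDIR (n = 2) and 44631 in RISDD (n = 3), so p53DD was seen wherever the labels place it. The Hras row averaged 1570 in NIL, 905 in SDD, 922 in SDDIR and 1138 in RISDD and passed in no comparison, so this row did not check the HRAS labels. Its NIL mean was raised by NIL C, at 2342 against 1238 in NIL A and 1129 in NIL B. Neurog2, Isl1 and Lhx3 were high in all groups, with means from 46124 (Neurog2, SDDIR) to 153704 (Lhx3, NIL). The NIL mean of Lhx3 was also raised by NIL C, at 258391 against 100451 in NIL A and 102271 in NIL B. Each of these genes was lower in both SDDIR libraries than in every SDD library. Neurog2 was 39669 and 52579 in SDDIR against 60593 to 79075 in SDD. Isl1 was 74614 and 95718 against 112760 to 141762, and Lhx3 70972 and 96814 against 103782 to 136750. Of Neurog2, Isl1 and Lhx3 only Isl1 passed in any comparison, 1.55-fold lower in SDDIR than in SDD (adjusted p = 0.0460). That call was lost without RISDD A, RISDD B, RISDD C, SDD B, SDD C, SDDIR A or SDDIR B (adjusted p = 0.0689 to 0.335, and 1.83e-04 to 0.335 over all alternatives). It was also lost with edgeR, GC correction, quantile or upper-quartile scaling, no filter, or neither trend nor robust moderation (adjusted p = 0.0567 to 0.212). The log2 change of Isl1 went from -0.63 to -0.30 with quantile scaling.

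**Figure D2:**
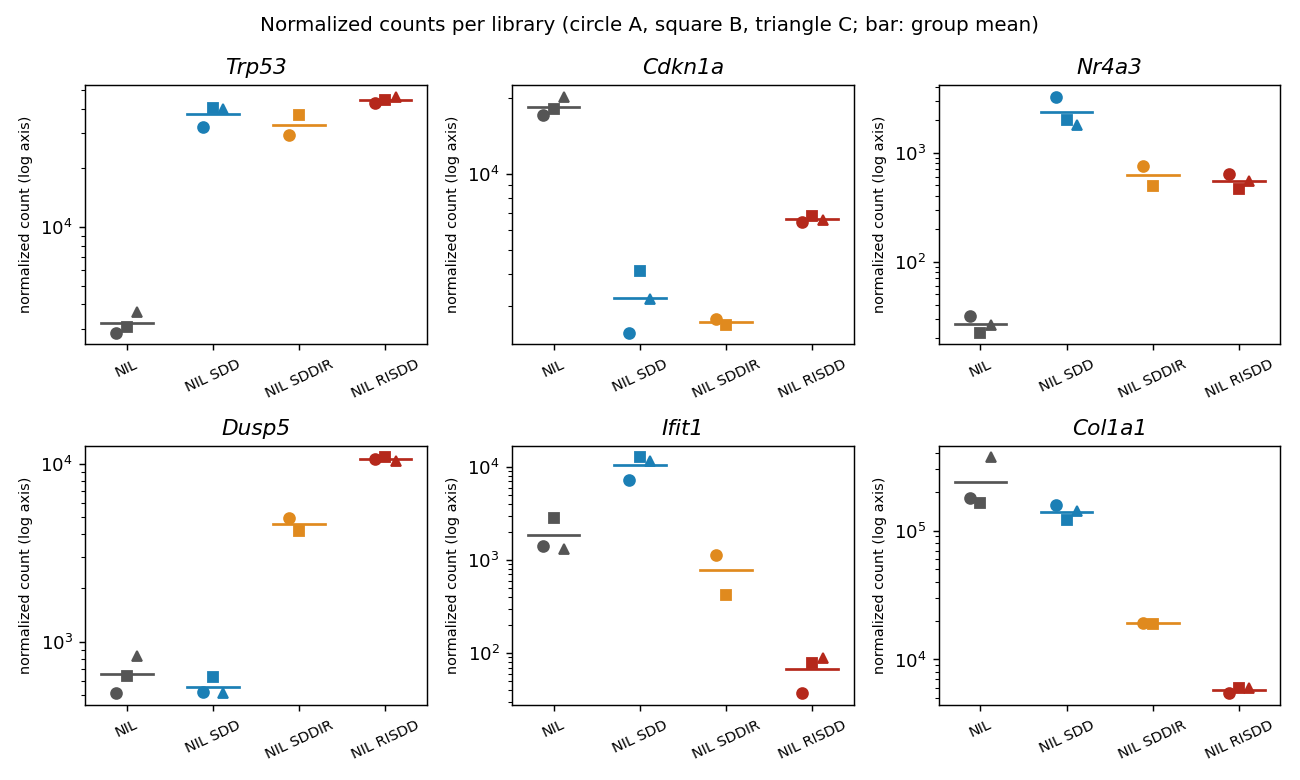
Signal per library on a log axis for Trp53, Cdkn1a, Nr4a3, Dusp5, Ifit1 and Col1a1 in NIL, SDD, SDDIR (n = 2) and RISDD (n = 3 for the others). Bars mark group means, for example 18484 in NIL and 3223 in SDD for Cdkn1a.

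SDD was compared with NIL to ask what blocking p53 changed during conversion, although RepSox, the SNAP stain and sort and a second virus came with it. The lists of immediate early, cell division and interferon genes were called higher in SDD, as were 3 neuronal lists. Those of p53 targets, fibroblast genes, and matrix proteases and the plasminogen system (which also holds protease inhibitors) were called lower. With all libraries none of these lists was called with an estimated correlation. Nr4a3, an orphan nuclear receptor, was 2334 ± 801 in SDD and 26.7 ± 4.74 in NIL (SD, n = 3 each), 81.9-fold higher (adjusted p = 9.66e-07). The other largest rises were Nr4a1 (47.0-fold), Egr4 (40.1-fold), Fosb (31.6-fold) and the neuronal imprinted gene Magel2 (16.5-fold). Nr4a1, Egr4 and Fosb, like Nr4a3, encode immediate early transcription factors. In that list 17 of 20 rose (20 adjusted over the list alone; camera adjusted p = 1.56e-15, and adjusted p = 0.0837 with an estimated correlation).

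The p53 target list was called lower. Perp, which acts in p53-dependent death and in cell adhesion, was 10.5-fold lower, Dcxr, a sugar reductase, 7.54-fold lower, and Cdkn1a, which encodes the CDK inhibitor p21, 5.87-fold lower (adjusted p = 3.72e-05). Of the p53 list 2 rose and 14 fell of 29 (3 and 17 adjusted over the list alone; camera adjusted p = 1.40e-06, and adjusted p = 0.0837 with an estimated correlation, or 0.0484 without NIL C). Btg2 and Plk2, also targets, were the 2 that rose. Division genes were called higher. Nusap1, Kif11 and Kif20b, which act on the spindle, were 3.56-fold, 3.10-fold and 3.09-fold higher. Of G2/M genes 27 of 30 rose (29 adjusted over the list alone; camera adjusted p = 2.75e-14, and adjusted p = 0.327 with an estimated correlation). Of G1/S genes 13 of 30 rose (16 adjusted over the list alone, 7 without SDD C, 27 without NIL C; camera adjusted p = 3.99e-06, and adjusted p = 0.331 with an estimated correlation).

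Of neuronal genes 3 lists were called higher, each with only a part of its members past the threshold. Nhlh1, a basic helix-loop-helix factor of new neurons, was 6.18-fold higher, Btg2 4.23-fold and St18 4.01-fold. In this proneural list 10 rose and 1 fell of 21 (13 and 2 adjusted over the list alone; camera adjusted p = 8.46e-04, and adjusted p = 0.327 with an estimated correlation). The neurofilament genes Nefl (4.03-fold), Ina (3.98-fold) and Nefm (3.92-fold) led the pan-neuronal list, where 9 rose and 1 fell of 37 (11 and 1 adjusted over the list alone, 5 rises without SDD A; camera adjusted p = 0.00196, and adjusted p = 0.327 with an estimated correlation). Among motor neuron genes Chodl was 3.20-fold higher, Prph, a peripheral neurofilament gene, 2.78-fold and Ebf1 2.70-fold. In the list 8 of 17 rose (8 adjusted over the list alone, 2 without SDD A; camera adjusted p = 0.00196, and adjusted p = 0.327 with an estimated correlation). The Chodl call was lost without NIL B, NIL C, SDD A or SDD C (adjusted p = 0.0654 to 0.111, and 8.88e-04 to 0.185 over all alternatives), and the Prph call without NIL B, SDD A or SDD C (adjusted p = 0.0533 to 0.0994, and 5.42e-04 to 0.0994 over all alternatives). Interferon genes were called higher too, led by Rsad2 (9.45-fold) and Mx1 (6.76-fold), which are antiviral effectors. Here 22 of 29 rose (26 adjusted over the list alone, 10 without SDD C; camera adjusted p = 6.59e-10, and adjusted p = 0.327 with an estimated correlation).

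Fibroblast and matrix lists were called lower. Mfap5, Dpt and Lox, a collagen crosslinker, were 4.06-fold, 3.07-fold and 2.80-fold lower. Of fibroblast genes 2 rose and 14 fell of 33 (2 and 19 adjusted over the list alone; camera adjusted p = 3.54e-06, and adjusted p = 0.327 with an estimated correlation). In the list of TGF-beta and contractile genes Id1, which BMP signals induce, was 10.2-fold higher, while Tagln, an actin-binding protein gene, was 4.85-fold lower and Pmepa1 3.55-fold lower. Of this list 2 rose and 12 fell of 28 (4 and 17 adjusted over the list alone; camera adjusted p = 7.84e-05, and adjusted p = 0.327 with an estimated correlation). RepSox, given to SDD and not to NIL, acts on this pathway. Serpine2 (12.2-fold lower) and Timp1 (5.62-fold lower) are protease inhibitors, and Adam8 (5.82-fold lower) is a protease. In their list of matrix proteases and the plasminogen system 1 rose and 15 fell of 25 (1 and 16 adjusted over the list alone, 9 falls without SDD C; camera adjusted p = 2.17e-07, and adjusted p = 0.0837 with an estimated correlation). The WNT pathway list was called lower, led by the WNT antagonists Dkk2 (3.98-fold), Nkd2 (3.37-fold) and Dkk3 (3.02-fold). In this list 5 of 17 fell (6 adjusted over the list alone, 3 without SDD A or SDD C; camera adjusted p = 0.0376, and adjusted p = 0.327 with an estimated correlation). The WNT call was lost without NIL C (adjusted p = 0.326, and 0.0144 to 0.327 over all alternatives), and with array weights or GC correction.

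Stard4, a sterol carrier gene, was 2.93-fold higher, and of cholesterol synthesis genes 7 of 24 rose (10 adjusted over the list alone, 3 without SDD A, 15 without NIL C; camera adjusted p = 0.00640, and adjusted p = 0.104 with an estimated correlation). Srxn1, an antioxidant gene, was 2.21-fold lower, and of NRF2 targets 4 of 18 fell (4 adjusted over the list alone, 1 without SDD A or SDD C; camera adjusted p = 0.00843, and adjusted p = 0.389 with an estimated correlation). Ndrg1 rose 2.31-fold within a glycolysis and hypoxia list called lower. Among all members 1 rose and 3 fell of 25 (1 and 4 adjusted over the list alone, 0 falls unless NIL A, NIL B or NIL C was the library left out, 7 falls without NIL C; camera adjusted p = 0.00516, and adjusted p = 0.327 with an estimated correlation). The MAPK feedback and output list was not called (adjusted p = 0.0691), although Ccnd1, the cyclin D1 gene, was 2.35-fold lower, and in all 1 rose and 6 fell of 20 (2 and 6 adjusted over the list alone, 3 falls without SDD C). Neither were the cytokines of the senescence secretome (adjusted p = 0.447), in which Ccl5 was 11.4-fold and Cxcl1 3.45-fold higher, and in all 2 rose and 2 fell of 18 (3 and 2 adjusted over the list alone).

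Leukocyte, epithelial and Schwann markers were called lower in SDD, none of them with an estimated correlation. The largest falls were Pierce1 (33.8-fold), Cx3cr1, a chemokine receptor of macrophages and microglia (27.9-fold), the granzyme gene Gzme (20.8-fold) and Dsp, a desmosomal gene of epithelia (19.0-fold, adjusted p = 9.62e-06). Leukocyte markers had a median log2 change of -2.04. Here 3 of 14 fell (8 adjusted over the list alone, 0 without NIL B, SDD A or SDD C, 8 without NIL A; camera adjusted p = 6.96e-05, and adjusted p = 0.352 with an estimated correlation). For epithelial markers 5 of 10 fell (5 adjusted over the list alone; camera adjusted p = 0.00623, and adjusted p = 0.257 with an estimated correlation). For Schwann and neural crest markers, with Ngfr 4.03-fold lower, 0 rose and 5 fell of 11 (1 and 6 adjusted over the list alone, 3 rises without NIL C, 2 falls without NIL A or SDD C; camera adjusted p = 0.0133, and adjusted p = 0.257 with an estimated correlation). The Schwann call was lost with a minimum value of 50 or with GC correction (adjusted p = 0.196 and 0.109, and 0.00535 to 0.257 over all alternatives).

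In SDD against NIL 2498 of 14207 tested genes changed, 1324 higher and 1174 lower (1330 by 2-fold or more, 794 higher and 536 lower). The balance turned with quantile scaling (1239 higher and 1425 lower), upper-quartile scaling (1190 and 1349), GC correction (1555 and 2136), edgeR (1220 and 1259) and DESeq2 (1777 and 1864). The count was 4128 without NIL C, 1441 without SDD A, 1533 without SDD B, 1231 without SDD C and 697 with only these 2 groups fitted. At 2-fold it was 868 without SDD A, 834 without SDD C and 585 with only these groups. Of 31 lists tested 18 were called, and 0 with an estimated correlation. Groups made by mixing NIL and SDD libraries gave as many as 19 called lists and at most 1 changed gene, though mixing also widens the error estimate. With only these 2 groups fitted, the calls of Kif20b, Nefl, Chodl, Prph, Adam8, Srxn1, Ccnd1, Cxcl1 and Cx3cr1 were lost (adjusted p = 0.0530 to 0.104). With array weights those of Nhlh1, Ina, Chodl, Rsad2, Tagln and Adam8 were lost (adjusted p = 0.0520 to 0.185), and with GC correction that of Chodl (adjusted p = 0.0565). Over all alternatives these genes ranged from 4.34e-08 (Tagln) to 0.185 (Chodl).

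**Figure D3:**
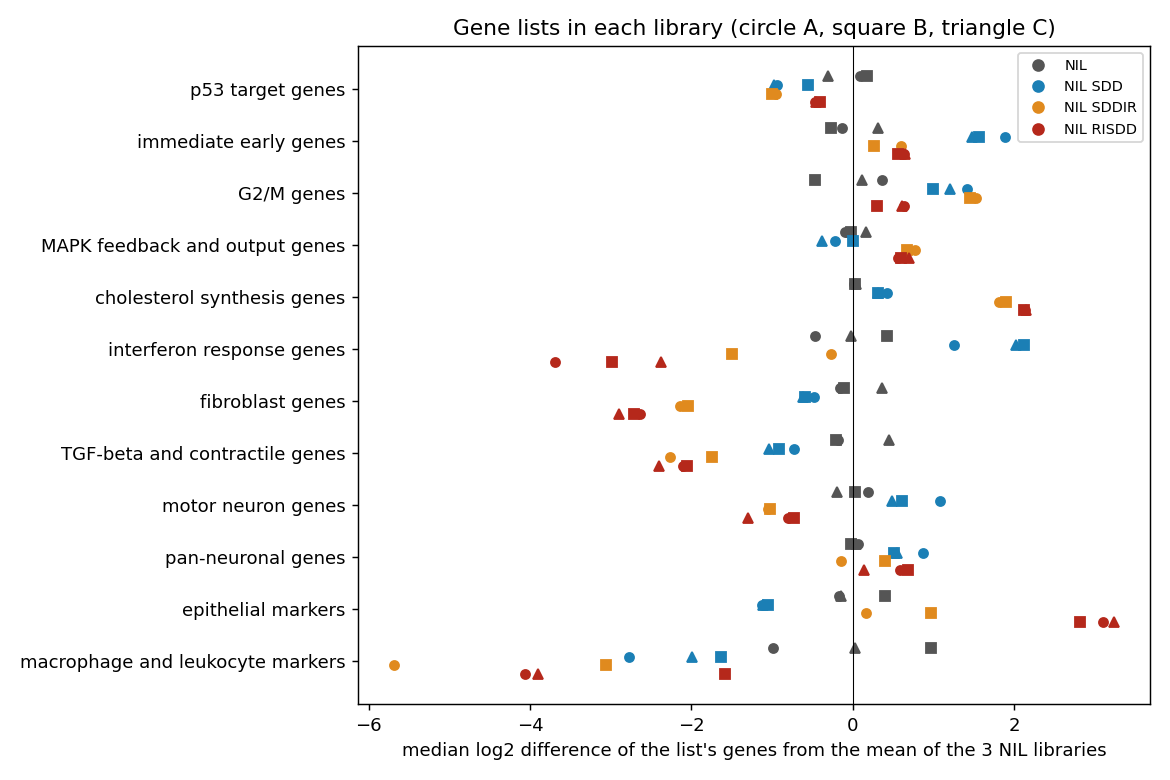
Median log2 difference from the mean of the NIL libraries for 12 gene lists, 1 point per library (NIL, SDD and RISDD n = 3, SDDIR n = 2). Each list was called by camera in 1 or more of the 4 comparisons.

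SDDIR was compared with SDD to ask what HRAS placed after the IRES added. Both groups had p53DD, RepSox and the SNAP sort. The values of Neurog2, Isl1 and Lhx3 were also lower in both SDDIR libraries than in every SDD library. This difference was not separated from HRAS. The list of MAPK feedback and output genes was called higher, as was that of cholesterol synthesis, and simple-epithelium keratins rose. Fibroblast, motor neuron and interferon lists were called lower. Of these lists only cholesterol synthesis was called with an estimated correlation. The dual-specificity phosphatase genes Dusp5 and Dusp4, feedback inhibitors of ERK, rose 8.20-fold and 7.38-fold, with Dusp5 at 4562 ± 533 in SDDIR and 556 ± 66.7 in SDD (SD, n = 2 and 3, adjusted p = 1.24e-05). Epha4, an ephrin receptor in the same list, was 7.01-fold lower. In the MAPK list 9 rose and 1 fell of 20 (11 and 1 adjusted over the list alone; camera adjusted p = 9.42e-05, and adjusted p = 0.226 with an estimated correlation).

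Fibroblast genes fell. Mfap4 was 43.5-fold lower, Lox 10.8-fold and the collagen gene Col1a1 7.29-fold, in a list where 1 rose and 27 fell of 33 (2 and 29 adjusted over the list alone; camera adjusted p = 1.71e-15, and adjusted p = 0.226 with an estimated correlation). Among TGF-beta and contractile genes Ccn2, a matricellular growth factor gene, was 21.5-fold lower, the elastin gene Eln 14.8-fold and Col8a1 9.06-fold. Of this list 2 rose and 18 fell of 28 (2 and 19 adjusted over the list alone, 11 falls without SDDIR A; camera adjusted p = 5.25e-07, and adjusted p = 0.293 with an estimated correlation). Motor neuron genes were called lower, with Chodl (51.5-fold), Prph (39.8-fold) and the GDNF receptor gene Gfra1 (5.73-fold). In this list 9 of 17 fell (11 adjusted over the list alone; camera adjusted p = 1.44e-06, and adjusted p = 0.226 with an estimated correlation). Pan-neuronal genes moved both ways and the list was not called (adjusted p = 0.0789). Dcx, which binds microtubules in migrating neurons, was 15.8-fold lower. Here 6 rose and 9 fell of 37 (6 and 11 adjusted over the list alone, 3 rises without SDDIR B, 4 falls without SDDIR A, 16 falls without NIL C). The Dcx call was lost without SDDIR A (adjusted p = 0.121, and 3.91e-06 to 0.121 over all alternatives).

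Cholesterol synthesis was the list that held here under every choice run for lists. Lists were not run with edgeR, DESeq2 or the fit with neither trend nor robust moderation. Msmo1, a sterol oxidase gene, was 6.19-fold higher (adjusted p = 5.54e-04). In this list 21 of 24 rose (21 adjusted over the list alone; camera adjusted p = 1.71e-15, and adjusted p = 0.00108 with an estimated correlation). Interferon genes fell, with Ifit1 (14.8-fold), Cxcl10 (14.2-fold) and the nucleic acid sensor gene Zbp1 (13.4-fold) first. Among all members 28 of 29 fell (29 adjusted over the list alone, 11 without SDDIR B; camera adjusted p = 4.87e-13, and adjusted p = 0.372 with an estimated correlation). Immediate early genes, higher in SDD than in NIL, were called lower here. Arc was 4.59-fold lower, Fos 4.10-fold and Nr4a3 3.70-fold. Here 13 of 20 fell (14 adjusted over the list alone, 7 without SDDIR B; camera adjusted p = 1.44e-06, and adjusted p = 0.293 with an estimated correlation). Secretome cytokines were called lower, led by Ccl2 (17.0-fold), Csf1 (9.11-fold) and Ccl7 (7.90-fold). Of this list 1 rose and 8 fell of 18 (1 and 8 adjusted over the list alone; camera adjusted p = 9.69e-04, and adjusted p = 0.372 with an estimated correlation).

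Egln3, a prolyl hydroxylase of the hypoxia response, was 3.23-fold higher, and of glycolysis and hypoxia genes 7 rose and 1 fell of 25 (7 and 1 adjusted over the list alone, 1 rise without SDDIR A or SDDIR B, 14 rises without NIL C; camera adjusted p = 0.0162, and adjusted p = 0.440 with an estimated correlation). Srxn1 was 2.90-fold higher, and of NRF2 targets 6 of 18 rose (6 adjusted over the list alone, 2 without SDDIR B; camera adjusted p = 0.0236, and adjusted p = 0.574 with an estimated correlation). This call was lost without NIL C or SDDIR B (adjusted p = 0.0540 to 0.0609, and 0.0104 to 0.574 over all alternatives). In the protease list the proteases Adamts5 (4.17-fold), Adamts1 (3.84-fold) and Mmp23 (3.67-fold) were lower. In this list 2 rose and 11 fell of 25 (3 and 13 adjusted over the list alone, 6 falls without SDDIR A; camera adjusted p = 0.0236, and adjusted p = 0.372 with an estimated correlation). It was lost without NIL C, SDD B or SDDIR A (adjusted p = 0.0534 to 0.0684, and 0.00529 to 0.372 over all alternatives), and with only these 2 groups fitted (adjusted p = 0.0745). p53 targets were not called (adjusted p = 0.555), though Fas (6.31-fold), Plk2 (5.66-fold) and Btg2 (3.59-fold) were lower, and in all 2 rose and 3 fell of 29 (2 and 3 adjusted over the list alone, 5 rises without NIL C, 6 falls without NIL C). G2/M genes were not called (adjusted p = 0.0631; 0 rose and 0 fell, also adjusted over the list alone, and 6 rose without NIL C).

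Epithelial genes gave the largest rises. Krt8 was 1159.5 ± 567 in SDDIR and 1.99 ± 1.73 in SDD (SD, n = 2 and 3), 433-fold higher, and its partner keratin gene Krt18 143-fold higher. Dsg2, a desmosomal cadherin gene (104-fold), Arap3 (59.9-fold) and Wnt7b (48.4-fold) followed. The largest falls were Shisa3 (88.7-fold), Col14a1 (88.2-fold, adjusted p = 5.34e-07), the BMP antagonist gene Nog (69.4-fold), the serotonin receptor gene Htr2c (67.6-fold) and Chodl. For epithelial markers 3 rose and 1 fell of 10 (3 and 1 adjusted over the list alone; camera adjusted p = 0.0108, and adjusted p = 0.293 with an estimated correlation). That call was lost without NIL C (adjusted p = 0.0609, and 5.83e-04 to 0.293 over all alternatives), and with array weights, GC correction or only these 2 groups fitted (adjusted p = 0.0509 to 0.0728). Leukocyte markers were called lower with 1 rise and 1 fall of 14 (1 and 6 adjusted over the list alone; camera adjusted p = 0.0343, or adjusted p = 0.768 with an estimated correlation). This was lost without NIL C, SDD B or SDDIR A (adjusted p = 0.0907 to 0.491, and 5.77e-05 to 0.768 over all alternatives), and 7 fell without SDDIR B. It was also lost with only these 2 groups fitted, a pseudocount of 10 or the repeated column counted (adjusted p = 0.0525 to 0.114).

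In SDDIR against SDD 3199 of 14207 tested genes changed, 1230 higher and 1969 lower (2038 by 2-fold or more, 645 higher and 1393 lower). It was 1673 without SDDIR A, 1695 without SDDIR B and 6337 without NIL C, a library outside this comparison that widens the shared error estimate. Leaving out an SDDIR library leaves that group with a single library, tested against the spread of the other groups. It was 6902 with array weights, 5361 with only these 2 groups and 5385 with GC correction. Of the changed genes 38.4% were higher, against 49.0% after quantile normalization and 58.5% after GC correction. Lists called numbered 13, and 1 with an estimated correlation.

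RISDD was compared with SDD to ask what HRAS placed before the IRES added, again with RepSox and the SNAP sort in common. Both groups had p53DD, but its fusion followed the IRES in RISDD and no IRES preceded it in SDD. Its protein level may therefore differ as well, and was not measured. The lists of MAPK feedback genes, EGFR ligands, epithelial genes and cholesterol genes were called higher. Those of fibroblast, interferon, motor neuron and division genes were called lower. Again only the cholesterol list was called with an estimated correlation. Dusp5 was 10555 ± 262 in RISDD and 556 ± 66.7 in SDD (SD, n = 3 each), 19.0-fold higher (adjusted p = 9.18e-08), the ephrin receptor gene Epha2 10.8-fold and Spred3, a RAS pathway inhibitor gene, 8.33-fold higher. In the MAPK list 11 rose and 2 fell of 20 (12 and 3 adjusted over the list alone; camera adjusted p = 6.57e-04, and adjusted p = 0.236 with an estimated correlation). Areg, an EGFR ligand gene, rose 52.0-fold, the cytokine gene Il11 19.1-fold and Btc, another EGFR ligand gene, 15.0-fold. Of growth factor genes 13 rose and 3 fell of 19 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00384, and adjusted p = 0.524 with an estimated correlation).

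Interferon genes fell throughout their list, with Ifit1 157-fold lower, Cxcl10 109-fold and Ifit3b 92.4-fold. Among all members 29 of 29 fell (29 adjusted over the list alone; camera adjusted p = 5.14e-15, and adjusted p = 0.435 with an estimated correlation). Fibroblast genes fell nearly as widely. Mfap4 was 218-fold lower, Lox 40.9-fold and Col1a1 23.8-fold, and 2 rose and 29 fell of 33 (2 and 29 adjusted over the list alone; camera adjusted p = 6.67e-14, and adjusted p = 0.186 with an estimated correlation). Among TGF-beta and contractile genes Col8a1 was 96.6-fold lower, Eln 39.0-fold and Ccn2 12.6-fold. Here 3 rose and 15 fell of 28 (4 and 15 adjusted over the list alone, 6 rises without NIL C; camera adjusted p = 0.00143, and adjusted p = 0.521 with an estimated correlation). Secretome cytokines split. The decoy receptor gene Tnfrsf11b was 125-fold lower and Csf1 21.5-fold lower, while Il1rn, which encodes an interleukin 1 antagonist, was 29.4-fold higher. Of this list 3 rose and 9 fell of 18 (3 and 11 adjusted over the list alone; camera adjusted p = 0.0195, and adjusted p = 0.526 with an estimated correlation). Immediate early genes were called lower, led by Egr2 (8.20-fold), Fos (8.11-fold) and Fosb (4.59-fold). In this list 12 of 20 fell (14 adjusted over the list alone; camera adjusted p = 6.57e-04, and adjusted p = 0.521 with an estimated correlation).

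Motor neuron genes were called lower, with Chodl 408-fold lower, Prph 59.3-fold and the guidance gene Slit3 20.7-fold. Among all members 4 rose and 11 fell of 17 (4 and 11 adjusted over the list alone, 1 rise without SDD C; camera adjusted p = 0.00340, and adjusted p = 0.521 with an estimated correlation). Pan-neuronal genes split and were not called (adjusted p = 0.880). Of this list 11 rose and 13 fell of 37 (11 and 15 adjusted over the list alone). Dcx was 86.6-fold lower, whereas the vesicle genes Scg2 and Snap25 were 14.3-fold and 12.6-fold higher. Division genes were called lower. Nusap1 (3.48-fold), Aurkb, a mitotic kinase gene (2.93-fold), and Kif11 (2.80-fold) led G2/M genes. Here 16 of 30 fell (17 adjusted over the list alone; camera adjusted p = 6.57e-04, and adjusted p = 0.622 with an estimated correlation). Tk1 (2.69-fold), Dscc1 (2.38-fold) and Ccne1 (2.15-fold) led G1/S genes. Of this list 15 of 30 fell (15 adjusted over the list alone; camera adjusted p = 0.00340, and adjusted p = 0.622 with an estimated correlation). p53 targets were not called (adjusted p = 0.108), with Perp 21.4-fold higher and Fas 16.1-fold lower. In this list 9 rose and 4 fell of 29 (11 and 5 adjusted over the list alone, 17 rises without NIL C).

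Msmo1 (7.95-fold) led cholesterol synthesis genes. In this list 22 of 24 rose (22 adjusted over the list alone; camera adjusted p = 1.11e-11, and adjusted p = 0.00305 with an estimated correlation). Srxn1 (7.38-fold), the transketolase gene Tkt (3.19-fold) and the exporter gene Abcc1 (2.25-fold) led NRF2 targets. Among all members 10 of 18 rose (10 adjusted over the list alone; camera adjusted p = 0.00218, and adjusted p = 0.521 with an estimated correlation). Egln3 was 4.45-fold higher, and the glucose transporter genes Slc2a1 and Slc2a3 were 3.96-fold and 3.39-fold higher. In their glycolysis and hypoxia list 11 rose and 2 fell of 25 (11 and 2 adjusted over the list alone, 6 rises without SDD A; camera adjusted p = 0.00946, and adjusted p = 0.521 with an estimated correlation). Nop56 (1.94-fold) led ribosome biogenesis genes. Here 11 of 25 rose (11 adjusted over the list alone, 7 without SDD A, 22 without NIL C; camera adjusted p = 6.57e-04, and adjusted p = 0.523 with an estimated correlation). Matrix proteases split and were not called (adjusted p = 0.880), with the stromelysin gene Mmp10 122-fold higher. Among all members 12 rose and 9 fell of 25 (12 and 9 adjusted over the list alone).

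Epithelial markers were again the largest rises. Krt8 was 1295-fold and Krt18 560.3-fold higher, followed by the chemokine receptor gene Ccr1 (345-fold), the protocadherin gene Pcdh8 (314-fold) and the peptidase gene Klk7 (305-fold). Cdh1, the E-cadherin gene, was at 195 ± 121 in RISDD and listed at 0 in every SDD library. For epithelial markers 9 rose and 1 fell of 10 (9 and 1 adjusted over the list alone; camera adjusted p = 1.10e-04, and adjusted p = 0.139 with an estimated correlation). Endothelial markers were called higher, with Cdh5 8.58-fold higher. Of this list 5 of 6 rose (5 adjusted over the list alone; camera adjusted p = 0.00340, and adjusted p = 0.139 with an estimated correlation). The largest falls were Kera, a corneal proteoglycan gene (492-fold), Chodl, Shisa3 (419 ± 170 in SDD and listed at 0 in every RISDD library), the interferon-induced GTPase gene Iigp1 (329-fold) and Serpina3n (252-fold).

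In RISDD against SDD 6046 of 14207 tested genes changed, 2840 higher and 3206 lower (3590 by 2-fold or more, 1424 higher and 2166 lower). The balance turned with quantile scaling (3345 higher and 2941 lower), GC correction (4689 and 3369), array weights (4933 and 4848), only these 2 groups fitted (4530 and 4439) and without NIL C (4550 and 4433). The count was 8983 without NIL C and moved past 1.5 times only with array weights (9781). Lists called numbered 16, and 1 with an estimated correlation; groups mixing RISDD and SDD libraries gave as many as 18. Across the 14207 genes the changes of SDDIR and RISDD against SDD correlated (Pearson r = 0.849). Simulated data in which no gene changed in any group gave 0.446, because SDD is in both. Real changes in either group alter r, so 0.446 is not the r that the shared libraries alone would give here. Among genes changed in both comparisons 1101 were higher in both, 1760 lower in both and 15 opposite; independent calls would give 246 and 444 for the first 2 counts. The r was 0.796 without SDDIR B. The covariance of the changes was 1.33, against 0.0786 in the simulated data. The SDD libraries common to both may thus account for about that much of the covariance. The simulated data gave a mean of 0.01 genes called in both comparisons. No gene changed in those data, so the part of these libraries in the real shared counts was not measured.

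**Figure D4:**
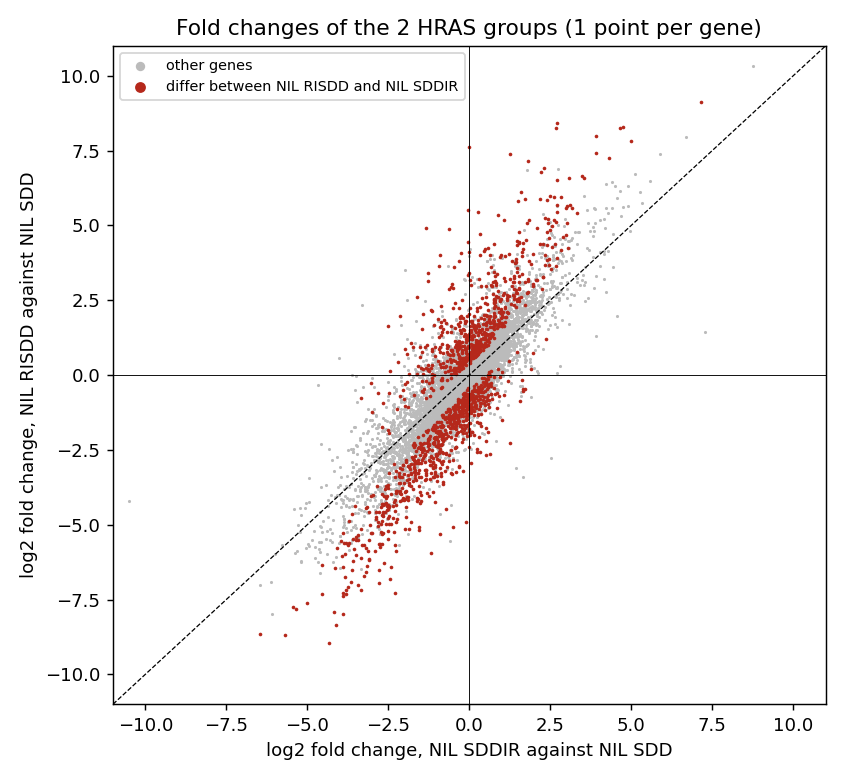
Log2 fold change of each of 14207 genes in SDDIR against SDD (horizontal) and RISDD against SDD (vertical), with the 1377 genes that differed between RISDD and SDDIR in red (n = 3 RISDD, 3 SDD, 2 SDDIR). The Pearson correlation was 0.849.

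RISDD was compared with SDDIR to ask what differed between the 2 placements of HRAS. The p53DD fusion changed places too, from before the IRES in SDDIR to after it in RISDD. The 2 moves cannot be told apart here. The lists of epithelial, growth factor, protease and p53 target genes were called higher in RISDD, with a part of each list past the threshold. Those of division, interferon and fibroblast genes were called lower. None of these calls held with an estimated correlation (adjusted p = 0.134 to 0.644). Krt20 was at 196 ± 14.4 in RISDD (SD, n = 3) and listed at 0 in both SDDIR libraries. Dmp1, a mineralized matrix gene (76.0-fold), Cdh1 (69.2-fold), Ccr1 (log2 5.73) and Klk7 (47.8-fold) were the next largest rises. The largest falls were the growth factor gene Ptn (32.5-fold, adjusted p = 1.10e-05), Spon1 (27.2-fold), Kera (24.3-fold), Sphkap (23.6-fold) and the Toll-like receptor cofactor gene Tril (21.2-fold). For epithelial markers 5 of 10 rose (7 adjusted over the list alone, 2 without RISDD C or SDDIR A; camera adjusted p = 1.29e-05, and adjusted p = 0.134 with an estimated correlation). For endothelial markers 3 of 6 rose (5 adjusted over the list alone, 0 unless NIL A, NIL B, NIL C, SDD A, SDD B or SDD C was the library left out; camera adjusted p = 0.00150, and adjusted p = 0.134 with an estimated correlation).

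Among G2/M genes Nusap1 was 3.44-fold lower. In this list 17 of 30 fell (26 adjusted over the list alone, 0 without SDDIR A; camera adjusted p = 2.33e-13, and adjusted p = 0.324 with an estimated correlation). The Nusap1 call was lost without SDDIR A or SDDIR B (adjusted p = 0.0700 to 0.0959, and 1.10e-05 to 0.0959 over all alternatives). Among interferon genes Mx2 was 12.3-fold and Ifit1 10.6-fold lower, with Ifit1 uneven in SDDIR (1130 in SDDIR A and 420 in SDDIR B). Among all members 21 of 29 fell (25 adjusted over the list alone, 1 without SDDIR A; camera adjusted p = 2.07e-14, and adjusted p = 0.324 with an estimated correlation). Mx2 was lost without SDDIR A (adjusted p = 0.0881, and 1.66e-08 to 0.0881 over all alternatives). Fibroblast genes were called lower, with Mfap4 5.01-fold and Lox 3.79-fold lower. Here 13 of 33 fell (18 adjusted over the list alone, 5 without SDDIR A, 23 without NIL C; camera adjusted p = 1.05e-08, and adjusted p = 0.324 with an estimated correlation). Mfap4 was lost without SDDIR A (adjusted p = 0.128, and 4.14e-06 to 0.128 over all alternatives). Col8a1, of the uncalled TGF-beta list (adjusted p = 0.671), was 10.7-fold lower.

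Areg was 6.08-fold higher among growth factor genes. Of this list 4 rose and 0 fell of 19 (13 and 2 adjusted over the list alone, 11 rises without NIL C; camera adjusted p = 1.16e-05, and adjusted p = 0.324 with an estimated correlation). Mmp10 was 24.8-fold higher among matrix proteases. In this list 9 rose and 3 fell of 25 (13 and 4 adjusted over the list alone, 2 rises without SDDIR A, 0 falls without SDDIR B; camera adjusted p = 0.00778, and adjusted p = 0.324 with an estimated correlation). The call of the gene Mmp10 was lost without SDDIR A or SDDIR B (adjusted p = 0.0534 to 0.0734, and 1.27e-09 to 0.0734 over all alternatives). For p53 targets 10 rose and 0 fell of 29 (13 and 2 adjusted over the list alone, 2 rises without SDDIR A or SDDIR B, 17 rises without NIL C, 3 falls without NIL C; camera adjusted p = 4.27e-04, and adjusted p = 0.225 with an estimated correlation). Pan-neuronal genes were called higher. Among all members 11 rose and 1 fell of 37 (11 and 2 adjusted over the list alone, 1 rise without SDDIR A, 5 falls without NIL C; camera adjusted p = 0.0431, and adjusted p = 0.601 with an estimated correlation). That call was lost without NIL C, RISDD A or SDDIR A (adjusted p = 0.0677 to 0.197, and 0.00697 to 0.601 over all alternatives). It was also lost with array weights, a minimum value of 50, GC correction, only these 2 groups fitted or the repeated column counted (adjusted p = 0.0504 to 0.107). G1/S genes were called lower (adjusted p = 0.00117, or adjusted p = 0.644 with an estimated correlation; 1 gene fell, 0 adjusted over the list alone, and 12 without NIL C). Ribosome biogenesis genes were called higher with 0 genes past the threshold and 5 without NIL C (0 adjusted over the list alone; adjusted p = 0.00117, or adjusted p = 0.601 with an estimated correlation). NRF2 targets (adjusted p = 0.0144, or adjusted p = 0.601 with an estimated correlation) and cholesterol genes (adjusted p = 0.0470, or adjusted p = 0.280 with an estimated correlation) were called higher with 1 gene each (also 1 each adjusted over the list alone), 5 and 10 without NIL C. The NRF2 call was lost without SDDIR A (adjusted p = 0.0814, and 0.00631 to 0.601 over all alternatives). The cholesterol call was lost without RISDD B, RISDD C, SDD A, SDD B, SDD C, SDDIR A or SDDIR B (adjusted p = 0.0509 to 0.0814, and 0.0240 to 0.280 over all alternatives). It was also lost with quantile or upper-quartile scaling, a pseudocount of 10 or no filter (adjusted p = 0.0565 to 0.181), and the list median went from 0.21 to 0.11 with quantile scaling.

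The MAPK list was not called (adjusted p = 0.173). Epha2 was 3.86-fold and Dusp5 2.32-fold higher and Spry1, a feedback inhibitor gene, 2.61-fold lower. Here 5 rose and 2 fell of 20 (7 and 2 adjusted over the list alone, 1 rise without SDDIR B). These calls were lost for Epha2 without SDDIR A or SDDIR B (adjusted p = 0.0660 to 0.109, and 1.16e-06 to 0.109 over all alternatives), for Dusp5 without SDDIR B (adjusted p = 0.0535, and 1.74e-07 to 0.0535 over all alternatives) and for Spry1 without SDDIR A (adjusted p = 0.0840, and 2.92e-06 to 0.0840 over all alternatives). Motor neuron genes were not called (adjusted p = 0.282), with the neurturin receptor gene Gfra2 9.18-fold higher and Chodl 7.92-fold and Slit3 3.73-fold lower. Of this list 3 rose and 5 fell of 17 (3 and 6 adjusted over the list alone, 1 rise without RISDD B, RISDD C, SDDIR A or SDDIR B, 3 falls without SDDIR A). Chodl was lost without SDDIR A (adjusted p = 0.0859, and 9.85e-07 to 0.0859 over all alternatives). Other single genes in uncalled lists were Igfbp3 (6.80-fold higher), Eomes (5.01-fold higher), the synaptic vesicle gene Sv2b (8.70-fold lower), the NOTCH target gene Heyl (4.56-fold lower) and the cartilage collagen gene Col11a1 (4.47-fold lower).

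In RISDD against SDDIR 1377 of 14207 tested genes changed, 659 higher and 718 lower (903 by 2-fold or more, 411 higher and 492 lower). The balance turned with a pseudocount of 10 (753 higher and 670 lower), array weights (2718 and 2628), only these 2 groups fitted (2667 and 2256) and without NIL C (2116 and 2066). Left out singly, it was 711 without RISDD A, 612 without RISDD B, 681 without RISDD C, 308 without SDDIR A, 446 without SDDIR B and 4182 without NIL C. At 2-fold the first 5 gave 595, 519, 553, 293 and 417. It was 5346 with array weights, 4923 with only these 2 groups, 2818 with GC correction, 2258 with DESeq2 and 2519 with the repeated column counted. Lists called numbered 13, and 0 with an estimated correlation.

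Another 8 lists were called in none of the 4 comparisons (adjusted p = 0.0586 to 0.987). These were CDK inhibitors and senescence genes, other spinal neuron subtypes, synapse and ion channel genes, the integrated stress and unfolded protein response, NOTCH pathway genes, mitochondrially encoded genes, and cartilage and adipocyte markers. Skeletal muscle markers, pluripotency markers and the delivered factors were not tested as lists. Outside the lists called in each comparison, median, mean and test differed in sign for NOTCH and endothelial genes in SDD against NIL, and for other spinal subtypes and Schwann markers in SDDIR against SDD. They also differed for CDK inhibitors and stress response genes in RISDD against SDD, and for secretome cytokines, synapse genes and Schwann markers in RISDD against SDDIR.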

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

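The weighing in this section was chosen after the results were seen, except for leaving out NIL C and the regrouping of samples, which were written before. Of the lists called between RISDD and SDDIR, 3 had medians of opposite sign in the 2 groups relative to SDD, though none was called against SDD in both. RISDD and SDDIR also differed in the place of the p53DD fusion relative to the IRES, which cannot be told apart from the placement of HRAS. The median change of each list between RISDD and SDDIR, taken gene by gene, is given last and need not equal the difference of the 2 medians before it. Matrix proteases had a median log2 change of -0.63 in SDDIR and 0.75 in RISDD, and 1.07 in RISDD against SDDIR (camera adjusted p = 0.00778, and adjusted p = 0.324 with an estimated correlation). p53 targets had -0.13 and 0.33, and 0.48 (adjusted p = 4.27e-04, and adjusted p = 0.225 with an estimated correlation). G2/M genes had 0.32 and -0.70, and -0.95 (adjusted p = 2.33e-13, and adjusted p = 0.324 with an estimated correlation), with 17 genes lower in RISDD and 0 without SDDIR A.

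NIL C stood apart from NIL A and NIL B. A trend with GC content fits, judged on the 10642 genes with a GC value and a mean of at least 100. The Spearman correlation between GC content and the deviation of NIL C was 0.826, against at most 0.299 in size in any library outside NIL. NIL C less NIL A gave 0.824, NIL C less NIL B 0.801 and NIL A less NIL B 0.151. The trend removed 56.0% of the variance and the SD fell from 0.944 to 0.626, still above the 0.239 to 0.372 of the other groups, so a further cause may remain. A higher dose of the delivered factors could not be told apart, since after removing the trend their 3 deviations were 0.719 SD (Lhx3), 1.47 SD (Neurog2) and 1.74 SD (Isl1). A different mix of male and female embryos could not be told apart either, since 4 Y-linked genes went from a median of -2.41 to -0.34 after the correction, as low as 4.86% of 10000 random gene sets.

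Immediate early genes were higher in SDD than in NIL. NIL C alone is excluded as the cause, because without it the list median was 1.75 and all 20 genes rose (adjusted p = 4.68e-18, and adjusted p = 0.0824 with an estimated correlation). RepSox and the SNAP stain and gate, used in every group except NIL, could not be told apart from p53DD, since no group had one without the other. The list medians against NIL were 1.66 in SDD, 0.41 in SDDIR and 0.62 in RISDD. The rise was thus smaller in the 2 HRAS groups, although they shared this handling and p53DD. These genes answer within minutes to handling, and the same groups all carried p53DD, so the rise may belong to either.

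Interferon genes were higher in SDD than in NIL and lower with HRAS than in SDD. RNA of leukocytes would raise the leukocyte list, but 0 of 14 members rose in SDD. The list had a median log2 change of -2.04 there (camera adjusted p = 6.96e-05, and adjusted p = 0.352 with an estimated correlation). Relative to the NIL mean, the list was at -0.98 in NIL A and 0.97 in NIL B. With this spread, a source in leukocytes was not seen but is not excluded. A second virus could not be told apart as a source of the rise, since SDDIR, which also received a second virus, had an interferon median of -0.94 against NIL while also carrying HRAS. For the fall in RISDD, Trp53, counted with p53DD, changed by 0.25 in log2 against SDD, which argues against a smaller amount of cassette RNA. The protein made from the cassette was not measured.

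Groups of 3 libraries can be mixed in only 10 ways, too few for a share under 0.05. Any real difference between the groups lies within the mixed groups and widens the error estimate. A low count of changed genes in a mixed grouping is therefore no support for the real one. For SDD and NIL the real grouping gave 2498 changed genes (1330 by 2-fold) and the highest other grouping 1 (1 by 2-fold), while it gave 18 called lists and the highest other 19, so 2 of the 10 groupings called as many. For RISDD and SDD the real grouping gave 6046 changed genes (3590 by 2-fold) and the highest other 0 (0 by 2-fold), with 16 called lists and 18 in the highest other, so 4 of the 10 called as many.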

How the results depend on the processing

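Of 262 named gene calls, 198 held with every library left out in turn and 223 held with every other setting, and none reversed; of 60 list calls 52 held with every library left out, but only 2 with every other setting, since most were lost with an estimated correlation. For lists, the other settings did not include edgeR, DESeq2 or the fit with neither trend nor robust moderation. With an estimated correlation 0 lists were called in SDD against NIL, 1 in SDDIR against SDD, 1 in RISDD against SDD and 0 in RISDD against SDDIR. Leaving out libraries gave 1231 (without SDD C) to 4128 (without NIL C) changed genes in SDD against NIL and 834 (SDD C) to 1542 (NIL A) by 2-fold. It gave 1673 (SDDIR A) to 6337 (NIL C) in SDDIR against SDD. It gave 308 (SDDIR A) to 4182 (NIL C) in RISDD against SDDIR, and 293 (SDDIR A) to 1339 (NIL C) by 2-fold. With an SDDIR library left out that group is a lone sample and its own spread was not measured. Without NIL C 95.2% of the genes called in SDD against NIL were kept. With only the 2 groups compared, SDD against NIL had 697 (585 by 2-fold), SDDIR against SDD 5361 and RISDD against SDDIR 4923 (1375 by 2-fold). Array weights gave 6902 in SDDIR against SDD, 9781 in RISDD against SDD and 5346 in RISDD against SDDIR (1560 by 2-fold). The estimate of the array weights stopped before its convergence tolerance was reached, so these counts are less certain than the others. GC correction gave 5385 in SDDIR against SDD and 2818 in RISDD against SDDIR; DESeq2 gave 2258 and the repeated column 2519 in the latter, and the cause was not tested. DESeq2 left the adjusted p of 11 genes empty in each comparison. The share of changed genes that were higher moved in SDDIR against SDD from 38.4% to 49.0% (quantile) and 58.5% (GC correction), in SDD against NIL to 42.1% and in RISDD against SDD from 47.0% to 58.2% (GC correction). The median of all genes in SDDIR against SDD became 0.10 with quantile scaling and 0.13 with GC correction. The correlation of the SDDIR and RISDD changes against SDD was 0.820 with DESeq2, 0.831 with edgeR, 0.874 at a minimum value of 50, 0.802 without a filter and 0.867 with a pseudocount of 10, and 0.796 (without SDDIR B) to 0.860 (without SDD B) with libraries left out. Some delivered factors that were not called changed sign. Hras in SDDIR against SDD was -0.0203 in log2 with array weights and ranged from -0.0313 (without SDD A) to 0.0893 (without SDD C). In SDD against NIL, Isl1 was -0.18 with GC correction and -0.0506 (without NIL A) to 0.26 (without NIL C). Lhx3 was 0.29 with array weights, 0.0688 with GC correction, 0.20 with quantile scaling and -0.41 (without NIL A) to 0.28 (without NIL C). Neurog2 was 0.27 with array weights, 0.21 with quantile scaling and -0.50 (without NIL B) to 0.26 (without NIL C). Libraries with the same letter were not treated as paired, since only 9 of 15 same-letter pairs had a residual correlation over 0.1 (lowest 2.25e-04, highest 0.271). As a hint of pairing from the data, all 15 were positive, and for 11 of 11 libraries the mean residual correlation with other groups was highest for its own letter. With the letter as a replicate block the counts were 2777, 3359, 6301 and 1440 (SDD against NIL, SDDIR against SDD, RISDD against SDD, RISDD against SDDIR), and 95.5%, 91.8%, 98.0% and 87.8% of the genes called without it were kept. If the column used as SDDIR B held replicate C, its letter in this fit would be wrong. Scaling to the ERCC spike-ins was not run.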

Other observations

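The 2 HRAS groups were also compared with NIL, a choice made after the planned results were seen. In limma 4759 genes changed in SDDIR and 6629 in RISDD. Besides HRAS, p53DD, RepSox, the SNAP sort and a second virus differed from NIL as well, so these changes cannot be credited to HRAS alone. Cholesterol synthesis genes rose in both, 22 of 24 in SDDIR (22 adjusted over the list alone, median log2 change 1.86, adjusted p = 0.00167 with an estimated correlation) and 22 of 24 in RISDD (22 adjusted over the list alone, 2.12, adjusted p = 0.00245 with an estimated correlation). Fibroblast genes fell, 27 of 33 in SDDIR (28 adjusted over the list alone, -2.08, camera adjusted p = 4.89e-16, and adjusted p = 0.131 with an estimated correlation) and 29 of 33 in RISDD (30 adjusted over the list alone, -2.77, camera adjusted p = 7.90e-16, and adjusted p = 0.263 with an estimated correlation). Interferon genes, higher in SDD than in NIL, were called lower than in NIL in both HRAS groups. In SDDIR 5 of 29 fell (4 adjusted over the list alone, -0.94, camera adjusted p = 0.0122, and adjusted p = 0.764 with an estimated correlation) and in RISDD 29 of 29 (29 adjusted over the list alone, -3.06, camera adjusted p = 2.83e-10, and adjusted p = 0.460 with an estimated correlation). The list median of SDDIR A, -0.27 relative to the NIL mean, lay inside the NIL libraries (-0.47 to 0.43), and that of SDDIR B was -1.49. Leukocyte markers were called lower with this, 12 of 14 in SDDIR (13 adjusted over the list alone, -4.35, camera adjusted p = 4.55e-05, and adjusted p = 0.474 with an estimated correlation) and 9 of 14 in RISDD with 1 rise (9 and 1 adjusted over the list alone, -3.15, camera adjusted p = 0.00606, and adjusted p = 0.666 with an estimated correlation). Epithelial markers were called higher in RISDD, with 6 rises and 2 falls of 10 (6 and 2 adjusted over the list alone, camera adjusted p = 0.0420, and adjusted p = 0.447 with an estimated correlation). So were endothelial markers, with 4 rises of 6 (5 adjusted over the list alone, camera adjusted p = 0.0179, and adjusted p = 0.263 with an estimated correlation). G2/M genes rose, 29 of 30 in SDDIR (30 adjusted over the list alone, camera adjusted p = 1.76e-12, and adjusted p = 0.409 with an estimated correlation) and 13 of 30 in RISDD (13 adjusted over the list alone, 0.55, camera adjusted p = 0.0138, and adjusted p = 0.792 with an estimated correlation).

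Mnx1, the gene that the reporter follows, lies outside the rule for naming genes and was chosen after its values were seen. It was 18.1 ± 11.9 in NIL, 94.2 ± 31.5 in SDD and 7.42 ± 6.56 in RISDD (SD, n = 3 each), and 9.91 ± 3.95 in SDDIR (SD, n = 2). In limma it rose in SDD against NIL (log2 2.46, adjusted p = 0.0249) and fell against SDD in SDDIR (-3.12, adjusted p = 0.00978) and in RISDD (-3.74, adjusted p = 7.98e-04).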
